A study of Mus musculus with 9 samples.

How the data were processed

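The deposited values were intensity values on a linear scale, 1 per probe set and array, for 9 single-channel arrays with 12422 probe sets. The labels named total RNA, and the software, summary method and scaling that made the deposited values are not given in the sources used here. The arrays had similar medians and lower quartiles but their upper quartiles spanned 0.22 on the log2 scale. The rule set for this case was quantile normalization between arrays when medians or upper quartiles differed by more than 0.1, so the values were quantile normalized and taken to log2. Values below a floor of 197, the percentile 25 of all values of all arrays, were raised to the floor. No detection calls came with the values, so the floor stood in for the limit of detection. Probe sets above the floor on fewer than 2 of the 9 arrays were not tested, which left 9686 probe sets for 7063 genes. Of the others, 2735 lay below the floor and 1 was empty on all arrays. Gene symbols came from the platform's annotation table, updated by gene identifier from a reference gene table of the mouse assembly GRCm38.p6. That step named 10833 probe sets with 1 gene each, left 396 with several genes and left 1193 unnamed. Probe sets with a family suffix, 1909 of those tested, can hybridise to related transcripts.

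Differences were tested with limma 3.58.1 in R 4.3.3. A single fit of 4 group means used all 9 arrays, with an intensity trend in the variance, 5 residual degrees of freedom and 4.20 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 9686 probe sets, and an adjusted p under 0.05 counted as past the threshold. The contrasts were the Rb-null minus the wild-type line averaged over the 2 media with equal weight, the same in serum and in serum-free medium, serum-free minus serum in each line, and the difference of the last pair, called the interaction. Changes are given as log2 differences with standard errors (SE) unless a fold is named. Where every array of the lower group lay at the floor, the fold is a lower bound.

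The 26 gene lists, with 730 distinct symbols, were DNA replication and nucleotide synthesis, G1/S cyclins with the RB-E2F family, CDK inhibitors, mitosis, DNA repair, p53 target genes, apoptosis, basal and luminal prostate epithelium markers, epithelial junctions, neuroendocrine markers, mesenchymal genes, smooth muscle, endothelial and leukocyte markers, interferon-stimulated genes with class I MHC, cytokines with NF-kB response genes, immediate-early genes, growth-arrest genes, cholesterol and fatty acid synthesis, glycolysis with hypoxia response, oxidative stress with glutathione genes, the unfolded protein and amino acid starvation response, extracellular proteases with their inhibitors, growth factors with their binding proteins, and cytosolic ribosomal proteins. On these lists 9 symbols matched by an older name and 2 had no match. Each gene was represented by its probe set with the highest mean. Lists were tested with camera from limma at its preset correlation between genes of 0.01, with adjustment over the lists, and again with a correlation estimated from the residuals. Members past the threshold were counted over all probe sets, and again with adjusted p-values taken over the list alone.

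The groups, the contrasts, the normalization rule, the floor, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. For each comparison of groups, the rule named the 8 probe sets with the highest and the 8 with the lowest log2 difference (12 and 12 for the averaged genotype difference) among those past the threshold with 1 gene symbol, no overlap between the arrays of the compared groups and a value above the floor in each group. It added up to 2 genes a direction whose lower group lay wholly at the floor, the 4 highest and the 4 lowest of the interaction, up to 4 members of each list with the smallest adjusted p, and 8 fixed genes of the Rb pathway.

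The procedure was run on simulated arrays of the same design with 200 changed probe sets. For the averaged genotype difference it called 74.6% of the probe sets with a true log2 change of 0.5, 94.0% of those with 1 and 93.9% of those with 2. For the interaction it called 23.9%, 73.1% and 93.9%. The other contrasts lay between these at a true change of 0.5, from 46.3% to 55.2%. No changed probe set was called in the wrong direction, and false calls made up 3.68% to 7.97% of all calls. The simulated noise was independent between probe sets, unlike the departure of wild-type serum 1 described below. These rates therefore need not hold for the real arrays.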

Results

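Gene expression was measured in a pair of mouse prostate epithelial cell lines, a wild-type line and a line that lacks a functional Rb1 gene, called Rb-null here. Rb1 encodes the retinoblastoma protein, which holds E2F transcription factors in check before DNA replication starts. Each line was grown with 5% fetal bovine serum or kept for 48 hours without serum. The 4 groups held 3 arrays of wild-type cells in serum, 2 of wild-type cells without serum, 2 of Rb-null cells in serum and 2 of Rb-null cells without serum. The labels name 1 line per genotype and do not say whether the arrays of a group came from separate cultures. The p-values therefore measure the spread between arrays only, each genotype difference is a difference between these lines, and the number of arrays limits the precision. Median deposited intensity ran from 445 to 474 across the arrays and the upper quartile from 991 to 1153.

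Rb1 was read first, as the targeted gene. Its tested probe set had deposited intensities of 713, 406 and 369 on the wild-type serum arrays and 383 and 361 on the wild-type serum-free arrays. The Rb-null arrays read 113 and 112 in serum and 166 and 160 without serum, all under the floor of 197. Averaged over the media Rb1 was lower in Rb-null cells by at least 2.15-fold (adjusted p = 0.000923). The bound was set by the floor, and with the floor at percentile 40 the call was lost (adjusted p = 0.126). In serum the log2 difference was -1.26 (SE 0.23, adjusted p = 0.00435) and without serum -0.94 (SE 0.25, adjusted p = 0.0222). The serum-free call was lost without any single serum-free array (adjusted p = 0.117 without wild-type serum-free 1, 0.0915 without wild-type serum-free 2, 0.0997 without Rb-null serum-free 1 and 0.0808 without Rb-null serum-free 2). A second probe set stayed below the floor on every array. Which part of Rb1 was deleted, and whether the probe sets lie in it, is not given in the sources used here.

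**Figure D1:**
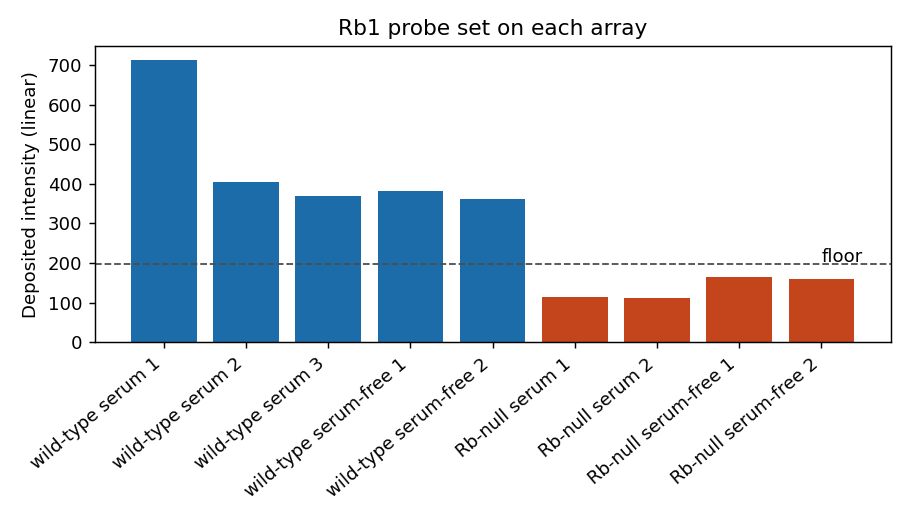
Deposited linear intensity of the tested Rb1 probe set on each of the 9 arrays, with blue bars for the wild-type line, red bars for the Rb-null line and a dashed line for the floor. All wild-type arrays lie between 361 and 713 and all Rb-null arrays between 112 and 166.

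The array wild-type serum 1 stood apart from the other wild-type serum arrays. Its rank correlations across probe sets with them were 0.983 and 0.986, against 0.997 between those 2. Its departures followed the genotype difference: among 775 probe sets that differed 1.5- to 2-fold between the lines in serum-free medium, 86.2% departed towards the Rb-null level, with a median of 0.29 against a genotype difference of 0.72. Among the 235 that differed 2- to 4-fold, 73.6% did so, with a median of 0.22 against 1.24. Among the 27 probe sets that differed at least 4-fold, 55.6% did so, with a median of 0.04 against 2.26. Of the probe sets called in the averaged genotype difference, wild-type serum 1 lay nearer to the other wild-type serum arrays than to the Rb-null serum arrays for 182 of the 198 changed at least 2-fold and for 2338 of the 4179 changed less. The total of called probe sets in each comparison is therefore also given without it, an alternative planned with the other arrays. If it shared array processing with the Rb-null arrays, leaving it out would not remove the effect of such processing.

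**Figure D2:**
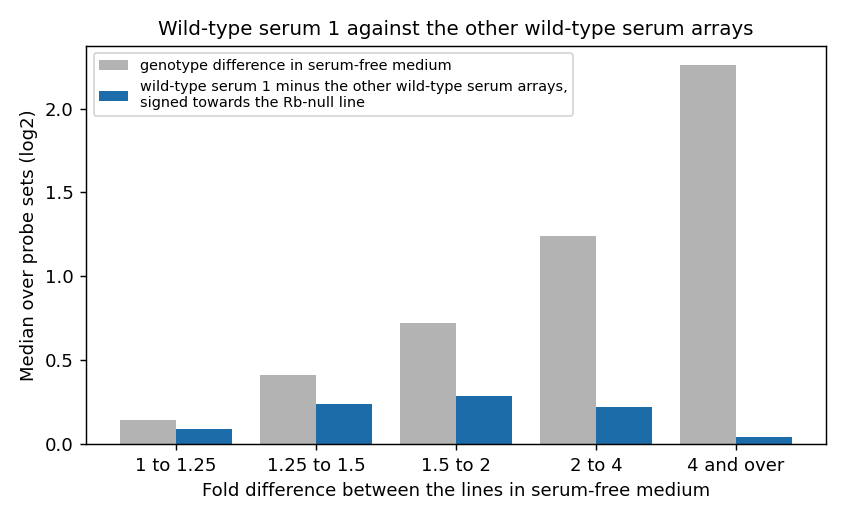
Median log2 difference over probe sets, grouped by their fold difference between the lines in serum-free medium, with grey bars for that genotype difference and blue bars for wild-type serum 1 minus the other wild-type serum arrays, signed towards the Rb-null line. The blue bar rises from 0.09 to 0.29 and falls to 0.04 in the group of at least 4-fold, while the grey bar rises throughout to 2.26.

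The averaged genotype comparison asked which genes differed between the Rb-null and the wild-type line on average over the 2 media. A gene could also pass through a large difference in a single medium. Lgals1, which encodes the secreted lectin galectin-1, was the named gene furthest above the wild-type level, 18.2-fold higher in Rb-null cells (log2 4.18, SE 0.05, adjusted p = 8.42e-11), with means of 448 and 9635 in serum. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 7.73-fold higher (adjusted p = 8.88e-07). B2m, the light chain of class I MHC, was 3.98-fold higher (adjusted p = 2.35e-07), as was Foxa1, a transcription factor of the prostate epithelium, at 3.94-fold. On the low side stood the transcription factor Sox11 at -3.09 (adjusted p = 6.27e-08), Plac8 at -2.98, the keratin Krt20 at -2.87 and Id2, an inhibitor of helix-loop-helix factors that binds the retinoblastoma protein, at -2.45 (adjusted p = 1.47e-08).

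Others among the higher genes were Plet1 at 2.37, Cyba, a subunit of NADPH oxidase, at 2.09, Igfbp3, a carrier of insulin-like growth factors, at 1.99, Ctse at 1.98, Nabp1 at 1.96, Erdr1 at 1.93, Slc20a1, a phosphate transporter, at 1.92 and Clu, a secreted chaperone, at 1.88. The probe sets of Cyba, Ctse, Erdr1 and Clu carry a family suffix. Cd200, a membrane glycoprotein, and Cxcl1, a chemokine that attracts neutrophils, lay at the floor on every wild-type array and were at least 5.46-fold and at least 4.52-fold higher in Rb-null cells. The lower genes included Akap12, a scaffold of protein kinase A, at -2.71, Cavin1, a component of caveolae, at -2.40, the ligand Wnt7b at -2.38, the phosphatase Ptpn13 at -2.21, the thrombin receptor F2r at -2.07, the lactate dehydrogenase subunit Ldhb at -2.05, the integrin Itga3 at -1.96 and the adenylate kinase Ak1 at -1.93. Igfbp7 lay at the floor on every Rb-null array and was at least 4.94-fold lower. All of these passed the threshold, with no overlap between the arrays of the lines, and all kept their calls without any single array.

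**Figure D3:**
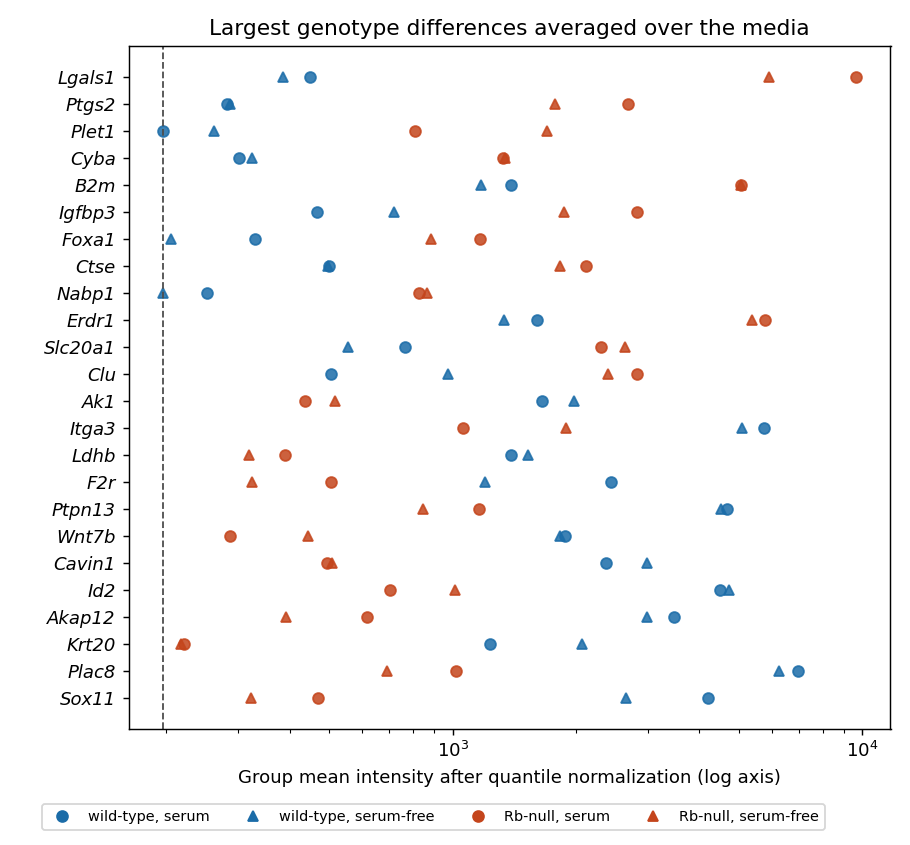
Group mean intensity on a log axis, after quantile normalization, of the 12 named genes furthest up and the 12 furthest down in the averaged genotype difference, with blue for the wild-type and red for the Rb-null line, circles for serum, triangles for serum-free medium and a dashed line for the floor. The gap between the lines is widest for Lgals1, with means of 448 and 9635 in serum.

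Across the fixed lists, genes of DNA replication were higher in Rb-null cells: 27 of 45 measured members were higher, 5 were lower and 13 did not pass, with a median of 0.34 (camera adjusted p = 2.26e-05, or adjusted p = 0.569 with an estimated correlation). Adjusted over the list alone, 29 were higher and 5 lower. Prim1, a DNA primase subunit, stood at 1.34 (SE 0.10), Gmnn, which encodes the licensing inhibitor geminin, at 1.27 (SE 0.11), Pcna, the sliding clamp, at 0.87 (SE 0.06) and Rpa1 at 0.68 (SE 0.05). Interferon-stimulated and class I MHC genes were higher for 19 of 30 and lower for 3 (19 and 4 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.00219, or adjusted p = 0.569 with an estimated correlation). Among them were B2m, Isg15 at 0.54 and Ifi202b, which lay at the floor in all wild-type arrays and was at least 2.65-fold higher. The unfolded protein and amino acid starvation list was higher for 16 of 27 and lower for 5 (17 and 7 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.00626, or adjusted p = 0.569 with an estimated correlation). Its stress transcription factors Ddit3 and Atf4 stood at 1.19 and 0.54, while the chaperone Pdia4 stood at -0.82. Against wild-type serum 1 alone, the mean difference in serum was smaller than against the other wild-type serum arrays for replication (0.14 and 0.31) and the unfolded protein list (0.08 and 0.17), but larger for the interferon list (0.29 and 0.21). Without that array the 3 lists passed with adjusted p of 1.30e-05, 0.0102 and 0.0102. Leaving it out cannot tell these shifts from array processing that it may share with the Rb-null arrays, a possibility left open below.

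The lists of cell cycle regulators did not pass. In the list of G1/S cyclins and the RB-E2F family, which includes Rb1 itself, 8 of 19 members were lower and 3 higher (8 and 4 adjusted over the list alone, adjusted p = 0.240). Cyclin D1 (Ccnd1) stood at -0.77 (adjusted p = 8.86e-07) and at -0.63 on its other probe set, and cyclin D3 (Ccnd3) at -0.58. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, stood at -0.42 (adjusted p = 0.000596) and at -0.44 on its other probe set. The CDK inhibitor list had 3 of 7 members lower and 0 higher (5 and 1 adjusted over the list alone, adjusted p = 0.281). In serum its mean difference was 0.00453 against wild-type serum 1 alone and -0.22 against the other wild-type serum arrays. The G1/S list read -0.37 and -0.27. E2f1 read 0.04 and -0.02 on its probe sets (adjusted p = 0.370 and 0.819), the Rb relative Rbl1 read 0.21 (adjusted p = 0.0610) and Cdkn2a -0.24 (adjusted p = 0.0680). Ccne1 was lower at -0.20 (adjusted p = 0.0164), a call lost without wild-type serum-free 1 or without Rb-null serum 1, and near 0 in the values as deposited (0.01, adjusted p = 0.944). Rbl2 was higher at 0.17 (adjusted p = 0.0237), a call lost without any of 5 arrays, wild-type serum-free 1 and 2, Rb-null serum 1 and 2 and Rb-null serum-free 1 (highest adjusted p = 0.0719).

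No list of markers of other cell types passed. Smooth muscle markers were lower for 5 of 7 and higher for 0, the same adjusted over the list alone (median -0.34, adjusted p = 0.0639, and 0.0427 without wild-type serum 1), with Smtn at -0.94 and Actg2 at -0.60. Endothelial markers were lower for 4 of 10 and higher for 0 by both counts (adjusted p = 0.245), with Pecam1 at -0.46. Neuroendocrine markers were lower for 3 of 10 by both counts (adjusted p = 0.240), with Uchl1 at -0.56 and Chga at -0.34. Leukocyte markers were lower for 1 of 13, Cd3g at -0.15, and for 0 adjusted over the list alone (adjusted p = 0.342). The Cd3g call held without only 2 of the 9 arrays, wild-type serum 1 and wild-type serum-free 2. Mesenchymal genes were higher for 4 of 21 and lower for 4 by both counts (adjusted p = 0.985). Tenascin C (Tnc), a matrix glycoprotein, lay at the floor in wild-type cells and was at least 3.21-fold higher, while Twist1 and Cdh2 each stood at -0.71. In serum, endothelial markers had a mean difference of 0.02 against wild-type serum 1 alone and -0.18 against the other wild-type serum arrays. Leukocyte markers also changed sign (0.11 and -0.12). Smooth muscle (-0.21 and -0.50), neuroendocrine (-0.06 and -0.15) and mesenchymal genes (0.16 and 0.15) kept their sign.

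No epithelial, cytokine or immediate-early list passed. Basal prostate markers were higher for 2 of 15 and lower for 4 by both counts (adjusted p = 0.539), with Sfn at -1.13 and Lamb3 at 0.56. Luminal markers were higher for 1 of 13 and lower for 4 (1 and 3 adjusted over the list alone, adjusted p = 0.826), with Hoxb13 at 0.33 and Cldn7 at -0.27. Epithelial junction genes were higher for 7 of 20 and lower for 6 (7 and 7 adjusted over the list alone, adjusted p = 0.559), with the desmosomal genes Pkp1 at 1.31 and Dsp at 1.22 and the tight junction gene Cldn1 at -0.98. Cytokine and NF-kB response genes were higher for 6 of 20 and lower for 6 (7 and 6 adjusted over the list alone, adjusted p = 0.559), with Il1a at 1.40. Immediate-early genes were higher for 9 of 32 and lower for 16 by both counts (adjusted p = 0.539), with Dusp1 at -1.29, Fos at -1.18 and Atf3 at 1.87, another probe set of which was called lower.

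Of the remaining lists, p53 target genes were higher for 1 of 12 and lower for 7 by both counts (adjusted p = 0.245), with Perp at -1.06. DNA repair genes were higher for 6 of 17 and lower for 2 by both counts (adjusted p = 0.245), mitosis genes higher for 9 of 35 and lower for 5 (8 and 5 adjusted over the list alone, adjusted p = 0.346) and apoptosis genes higher for 2 of 18 and lower for 6 (2 and 7, adjusted p = 0.445). Oxidative stress genes were higher for 7 of 30 and lower for 10 by both counts (adjusted p = 0.812), with the glutathione transferase Gstm1 at -1.29. Growth factor genes were higher for 9 of 34 and lower for 15 (9 and 17, adjusted p = 0.245) and extracellular protease genes higher for 5 of 24 and lower for 6 by both counts (adjusted p = 0.792), with the membrane protease Mmp14 at -1.28. Glycolysis and hypoxia genes were higher for 3 of 20 and lower for 6 by both counts (adjusted p = 0.812), cholesterol genes higher for 8 of 24 and lower for 2 by both counts (adjusted p = 0.347), growth-arrest genes higher for 5 of 17 and lower for 4 by both counts (adjusted p = 0.915) and ribosomal proteins higher for 1 of 19 and lower for 6 (1 and 4, adjusted p = 0.727). Median and mean differed in sign for the mesenchymal (-0.05 and 0.03), cytokine (-0.08 and 0.20), immediate-early (-0.15 and 0.01), cholesterol (-0.00 and 0.12) and luminal lists (0.00 and -0.03). The test followed the mean except for the immediate-early list, which it put down.

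In total 4377 of 9686 probe sets passed in the averaged genotype difference, 2107 higher and 2270 lower, and 6074 without wild-type serum 1. For 2156 of the 4377 the arrays of the lines did not overlap. At 2-fold or more, 127 were higher and 71 lower. The share of higher probe sets was 48.1%, against 69.3% in the values as deposited and 60.7% with arrays scaled to a common median, so the balance of directions depended on the scaling. It was 42.9% without wild-type serum 1. Among 375 genes with at least 2 called probe sets, 84 had called probe sets in both directions.

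In serum Lgals1 again stood furthest above the wild-type level among the named genes. It was 21.5-fold higher (adjusted p = 9.73e-10), Ptgs2 9.69-fold, Igfbp3 6.05-fold and Clu 5.59-fold higher, and the serum- and glucocorticoid-induced kinase Sgk1 stood at 2.08. Cyba, Ctse and B2m stood at 2.13, 2.08 and 1.88. Tnc was at least 6.60-fold and Cd200 at least 5.98-fold higher than the floor of the wild-type arrays. Sox11 stood at -3.15, Plac8 at -2.77, Wnt7b at -2.71, Id2 at -2.67, Krt20 at -2.49, Akap12 at -2.48, Itga3 at -2.43 and the plexin Plxnb2 at -2.28. Igfbp7 and the imprinted gene Peg3 lay at the floor in Rb-null cells in serum and were at least 6.25-fold and at least 5.07-fold lower.

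Replication genes were higher in serum for 20 of 45 and lower for 2 (23 and 4 adjusted over the list alone, median 0.27, adjusted p = 0.000612, or adjusted p = 0.544 with an estimated correlation), with Gmnn at 1.19 and Cdc6, which loads the replicative helicase, at 0.82. Interferon and class I MHC genes were higher for 11 of 30 and lower for 1 (12 and 1, adjusted p = 0.000870, or adjusted p = 0.3 with an estimated correlation), with Isg15 at 0.71. The unfolded protein list was higher for 9 of 27 and lower for 4 (13 and 4, adjusted p = 0.0228, or adjusted p = 0.544 with an estimated correlation), with Hspa5 at 0.72. Lower lists were the p53 targets, lower for 5 of 12 and higher for 1 (7 and 1, adjusted p = 0.0223, or adjusted p = 0.3 with an estimated correlation), the smooth muscle markers, lower for 2 of 7 by both counts (adjusted p = 0.0239, or adjusted p = 0.544 with an estimated correlation), and the G1/S list, lower for 6 of 19 and higher for 1 (7 and 1, adjusted p = 0.0349, or adjusted p = 0.3 with an estimated correlation). Without wild-type serum 1 the p53 and G1/S lists no longer passed (adjusted p = 0.0508 and 0.185), while their medians moved little, from -0.19 to -0.19 and from -0.14 to -0.12. Against wild-type serum 1 alone, the mean difference was -0.21 for smooth muscle markers and 0.04 for mitosis genes. Against the other wild-type serum arrays it was -0.50 and 0.19. The G1/S list went the other way (-0.37 and -0.27), and the p53 targets stayed at -0.28. Mitosis genes were higher for 10 of 35 and lower for 2 (11 and 3, adjusted p = 0.0418, or adjusted p = 0.677 with an estimated correlation). That call was lost without wild-type serum 2 (adjusted p = 0.108), wild-type serum 3 (0.163) or Rb-null serum 2 (0.0639). Counts in brackets are those adjusted over the list alone.

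In serum-free medium Lgals1 was 15.3-fold higher in Rb-null cells (adjusted p = 4.61e-09), Plet1 6.51-fold, Ptgs2 6.16-fold and the aldehyde dehydrogenase Aldh2 5.01-fold higher. Slc20a1, Mtm1, B2m and Foxa1 stood between 2.10 and 2.25. The stress-induced chromatin factor Nupr1 lay at the floor in wild-type cells and was at least 6.24-fold higher, and Cd200 at least 4.98-fold. Krt20 stood at -3.25, Plac8 at -3.18, Sox11 at -3.03, Akap12 at -2.93, Cavin1 at -2.55, Ptpn13 at -2.41, Ldhb at -2.26 and Id2 at -2.22, and Igfbp7 was at least 3.91-fold lower. Replication genes were higher for 21 of 45 and lower for 3 (23 and 4 adjusted over the list alone, median 0.32, adjusted p = 2.53e-05, or adjusted p = 0.595 with an estimated correlation), with Prim1 at 1.85, Pcna at 1.15 and the helicase subunit Mcm3 at 1.04. The unfolded protein list was higher for 14 of 27 and lower for 3 (16 and 4 adjusted over the list alone, adjusted p = 0.00307, or adjusted p = 0.595 with an estimated correlation), a call lost without Rb-null serum-free 2 (adjusted p = 0.0635). Interferon and class I MHC genes were higher for 11 of 30 and lower for 1 (11 and 2 adjusted over the list alone, adjusted p = 0.0185, or adjusted p = 0.595 with an estimated correlation), a call lost without Rb-null serum-free 1 (adjusted p = 0.0625). Rbl1 was higher at 0.52 (adjusted p = 0.0112), a call lost without wild-type serum-free 1, wild-type serum-free 2 or Rb-null serum-free 1 (highest adjusted p = 0.0779).

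In serum 2287 probe sets passed, 1279 higher and 1008 lower, and 4376 without wild-type serum 1. Leaving out Rb-null serum 1 or Rb-null serum 2 gave 1049 and 877. In serum-free medium 2971 passed, 1628 higher and 1343 lower, 4981 without wild-type serum 1, 1159 without wild-type serum-free 1, 1392 without wild-type serum-free 2 and 1289 without Rb-null serum-free 1. Each of the last 3 leaves a group with a single array. The share of higher probe sets was 55.9% in serum and 54.8% in serum-free medium, against 73.4% and 77.6% in the values as deposited and 68.0% and 68.1% with median scaling. Without wild-type serum 1 the majority turned to lower, with 48.0% and 45.3% higher, as it did with array quality weights (44.9% and 47.9%). The media shared 956 higher probe sets, where independence would give 215, and 655 lower ones, where it would give 140. Both comparisons took the variance of a probe set from the same fit, which by itself can raise the overlap above independence. Of 1621 probe sets called in both media, 10 went in opposite directions, and the differences correlated at r = 0.81 across probe sets, which are not independent replicates.

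Serum withdrawal in wild-type cells, the comparison of 48 hours without serum against 5% serum, lowered genes of cell division. The mitotic kinase Plk1 changed by -2.66 (SE 0.13, adjusted p = 3.59e-06), the proliferation marker Mki67 by -2.58 (SE 0.12), the ribonucleotide reductase subunit Rrm2 by -2.52 (SE 0.10), Birc5, which encodes survivin, by -2.50 (SE 0.08), Ect2 by -2.48, the activin antagonist Fst by -2.34, the repressor E2f8 by -2.28 and the topoisomerase Top2a by -2.26. Kif11, a spindle motor, reached the floor and was at least 3.64-fold lower. Upwards, the immediate-early factor Fos rose by 1.79 (SE 0.14), the adaptor Blnk by 1.70, Grcc10 by 1.64, Reep6 by 1.49, Egr1 by 1.40, Ddit3 by 1.26, the translation inhibitor Pdcd4 by 1.24 and Kank3 by 1.22. The gap junction gene Gjb2 rose at least 2.00-fold and Pkhd1 at least 1.95-fold from the floor.

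Of 35 mitosis genes in wild-type cells 30 fell and 0 rose (32 and 0 adjusted over the list alone), with a median of -1.55 (adjusted p = 1.52e-37, or adjusted p = 0.0877 with an estimated correlation). Of 45 replication genes 32 fell and 0 rose (34 and 1), with a median of -0.76 (adjusted p = 8.21e-25, or adjusted p = 0.0877 with an estimated correlation), among them Mcm3, which fell by 1.51, and Rrm1, which fell by 1.41. Cholesterol and fatty acid synthesis genes fell for 13 of 24 and rose for 0 (16 and 0, adjusted p = 9.15e-09, or adjusted p = 0.138 with an estimated correlation), with the desaturase Scd1 at -1.36, Idi1 at -1.20 and the fatty acid synthase Fasn at -0.69. The G1/S list fell for 6 of 19 and rose for 1 (7 and 1, adjusted p = 0.00304, or adjusted p = 0.0877 with an estimated correlation), with cyclin A2 (Ccna2) at -1.08 and Rbl1 at -0.98. DNA repair genes fell for 3 of 17 by both counts (adjusted p = 0.0346, or adjusted p = 0.155 with an estimated correlation), a call lost without wild-type serum 3 (adjusted p = 0.0990) or wild-type serum-free 2 (0.130). Counts in brackets are those adjusted over the list alone.

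Lists that rose in wild-type cells began with growth-arrest genes, up for 7 of 17 and down for 0 by both counts (adjusted p = 0.000348, or adjusted p = 0.0877 with an estimated correlation). The non-coding host gene Gas5 rose by 0.96, Txnip, an inhibitor of thioredoxin, by 0.85, Ddit4 by 0.79 and Btg1 by 0.70. Ribosomal proteins rose for 3 of 19 and fell for 0 (4 and 0, adjusted p = 0.0142, or adjusted p = 0.155 with an estimated correlation), with Rpl22 at 1.13. Oxidative stress genes rose for 4 of 30 and fell for 1 (9 and 3, adjusted p = 0.0232, or adjusted p = 0.226 with an estimated correlation), with the epoxide hydrolase Ephx1 at 0.93 and glutathione reductase (Gsr) at 0.65. Of the inhibitors, Cdkn2b rose by 0.73 and Cdkn1a by 0.49, while Cdkn3, a phosphatase whose transcript peaks in dividing cells, fell by 0.90. The Cdkn1a call was lost without wild-type serum-free 2 (adjusted p = 0.0525). Glycolysis genes rose for 2 of 20 and fell for 3 (4 and 5, adjusted p = 0.219), with lactate dehydrogenase A (Ldha) at -0.67. Smooth muscle markers fell for 2 of 7 (adjusted p = 0.656, median 0.11, mean -0.00). Counts in brackets are those adjusted over the list alone.

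The remaining lists did not pass in wild-type cells. In all, 1536 probe sets passed on withdrawal in wild-type cells, 640 higher and 896 lower, with 22 higher and 123 lower at 2-fold or more. Without wild-type serum 1 there were 1963, without wild-type serum-free 1 there were 729 and without wild-type serum-free 2 there were 667. The share of higher probe sets was 41.7%, against 25.7% in the values as deposited, 47.8% without wild-type serum 1 and 50.7% with array quality weights.

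Serum withdrawal in Rb-null cells also lowered genes of cell division. Birc5 changed by -3.12 (SE 0.08, adjusted p = 2.52e-07), Mki67 by -2.79, Plk1 by -2.63, Pclaf, which binds the replication clamp, by -2.54, Top2a by -2.33, and the spindle genes Bub1, Ccnb2 and Kif11 by -2.30 each. Cip2a reached the floor and was at least 5.15-fold lower. Upwards, the annexin Anxa8 rose by 1.74 (SE 0.09, adjusted p = 6.04e-06), Reep6 by 1.63, Txnip by 1.63, Nupr1 by 1.48, the stress-responsive gene Ndrg1 by 1.46, Stbd1 by 1.44, Sgip1 by 1.41 and Cpt1a, which carries fatty acids into mitochondria, by 1.40. The microsomal glutathione transferase Mgst1 rose at least 3.23-fold and Rnase4 at least 2.08-fold from the floor.

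Mitosis genes fell in Rb-null cells for 29 of 35 and rose for 0 (31 and 0 adjusted over the list alone), with a median of -1.73 (adjusted p = 1.71e-42, or adjusted p = 0.0705 with an estimated correlation). Replication genes fell for 28 of 45 and rose for 0 (34 and 0), with a median of -0.42 (adjusted p = 1.63e-20, or adjusted p = 0.0934 with an estimated correlation). Rrm2 fell by 2.27, Cdc6 by 2.20 and Rrm1 by 1.12. Cholesterol and fatty acid synthesis genes fell for 12 of 24 and rose for 0 (15 and 0, adjusted p = 1.40e-08, or adjusted p = 0.120 with an estimated correlation), with Idi1 at -1.62, Elovl6 at -0.85 and Sqle at -0.82. The G1/S list fell for 5 of 19 and rose for 2 (7 and 2, adjusted p = 0.00532, or adjusted p = 0.0934 with an estimated correlation), with Ccna2 at -1.24 and Ccnd1 at -0.48. DNA repair genes fell for 3 of 17 by both counts (adjusted p = 0.0281, or adjusted p = 0.125 with an estimated correlation), a call lost without Rb-null serum-free 2 (adjusted p = 0.0634). Counts in brackets are those adjusted over the list alone.

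Growth-arrest genes rose in Rb-null cells for 9 of 17 and fell for 1 by both counts (adjusted p = 0.000417, or adjusted p = 0.0934 with an estimated correlation), with Txnip, Cebpb at 1.11 and Gas5 at 1.05. The p53 targets rose for 5 of 12 and fell for 0 (5 and 1, adjusted p = 0.00329, or adjusted p = 0.0934 with an estimated correlation), with Gadd45a at 1.14. Oxidative stress genes rose for 6 of 30 and fell for 1 (7 and 2, adjusted p = 0.00532, or adjusted p = 0.125 with an estimated correlation), with Ephx1 at 1.13 and Gsta4 at 0.86. Ribosomal proteins rose for 4 of 19 and fell for 0 (6 and 0, adjusted p = 0.00674, or adjusted p = 0.125 with an estimated correlation). The unfolded protein list rose for 6 of 27 and fell for 1 (7 and 3, adjusted p = 0.0478, or adjusted p = 0.553 with an estimated correlation), with Ddit3 at 1.38 and Trib3 at 1.22. That call was lost without wild-type serum 3, wild-type serum-free 1, wild-type serum-free 2, Rb-null serum 2 or Rb-null serum-free 2 (highest adjusted p = 0.304). Counts in brackets are those adjusted over the list alone.

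The remaining lists did not pass in Rb-null cells. The matrix gene Tnc fell, at -2.08, although mesenchymal genes did not pass as a list (1 rose and 4 fell, adjusted p = 0.0681). In Rb-null cells 1348 probe sets passed on withdrawal, 726 higher and 622 lower, with 56 higher and 95 lower at 2-fold or more. Without wild-type serum 1 there were 2280, without Rb-null serum 1 there were 643, without Rb-null serum 2 there were 497 (43.1% higher), without Rb-null serum-free 1 there were 793 (49.7% higher) and without Rb-null serum-free 2 there were 805. The share of higher probe sets was 53.9%, against 44.4% in the values as deposited, so the main direction turned with the scaling. The lines shared 360 higher probe sets, where independence would give 48.0, and 425 lower ones, where it would give 57.5. The shared variance of the fit can raise this overlap too. Of 794 called in both, 9 went in opposite directions, and the changes correlated at r = 0.69 across probe sets. With an estimated correlation and without wild-type serum 1, a pair of choices combined after seeing the data, the mitosis list passed in wild-type (adjusted p = 0.00737) and Rb-null cells (adjusted p = 0.00790), and so did the replication list (adjusted p = 0.0229 and 0.0335).

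**Figure D4:**
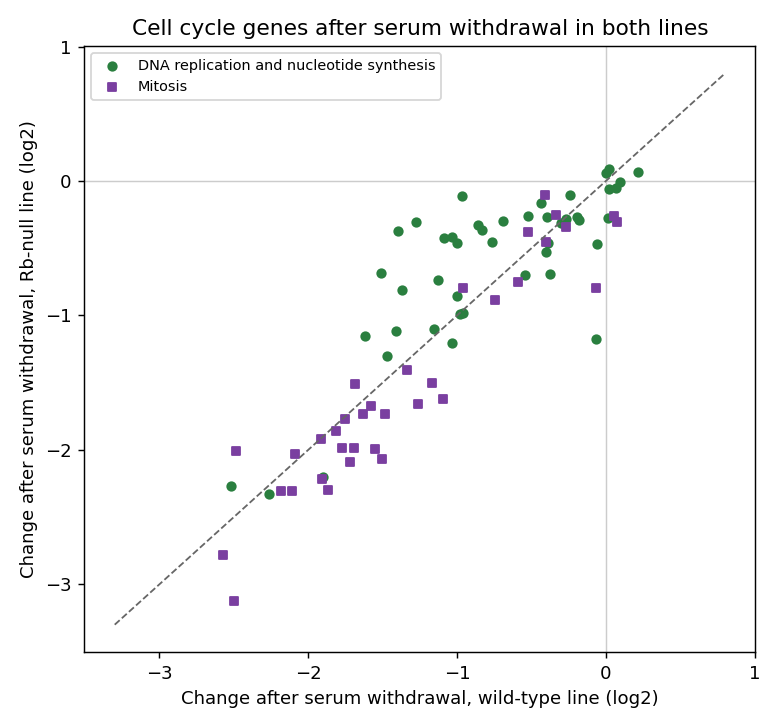
Log2 change after serum withdrawal of each measured gene of the replication list (green circles) and the mitosis list (purple squares), in the wild-type line on the horizontal and in the Rb-null line on the vertical axis, with a dashed line of equal change. The list medians are -0.76 and -0.42 for replication and -1.55 and -1.73 for mitosis. The gap between such medians is not the typical difference per gene. Taken gene by gene, the median difference of responses is 0.0654 for replication and -0.16 for mitosis.

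The interaction tested whether the response to serum withdrawal differed between the lines. Several calls rested on values at the floor, where a response in 1 of the lines could not be measured. Nupr1 and Tnc lay at the floor on every wild-type array, so their interactions of 1.48 (adjusted p = 0.00433) and -2.12 (SE 0.09, adjusted p = 1.16e-05) are the change in Rb-null cells alone. Mgst1 lay at the floor in serum in both lines and on 1 of 2 wild-type serum-free arrays, and its interaction of 1.54 (SE 0.15, adjusted p = 0.00368) is no exact difference of responses. The inducible heat shock genes Hspa1a and Hspa1b rose in wild-type cells by 0.69 and 0.98 and fell in Rb-null cells by 0.90 and 1.10 (interactions of -1.59 and -2.08, adjusted p = 0.000460 and 0.00433). The matrix gene Sparc, at -1.81 and at the floor on every wild-type serum array, and the helicase subunit Mcm3, at 1.42, also passed (adjusted p = 0.0254 and 0.0312). Peg3 passed at 1.48 (adjusted p = 0.0487), but this probe set lay at the floor on every Rb-null array, so the value is the fall in wild-type cells against a response that could not be measured. The other tested probe sets of Peg3 did not pass (0.96 and 0.09, adjusted p = 0.0769 and 0.763). Calls for Nupr1 and Hspa1b were lost without wild-type serum-free 2 (adjusted p = 0.0513 for each). The Sparc call held only without wild-type serum 1, wild-type serum-free 1 or Rb-null serum-free 1 (highest adjusted p = 0.176). Peg3 held only without wild-type serum 1 or wild-type serum 3 (highest adjusted p = 0.242), and Mcm3 only without a wild-type serum array (highest adjusted p = 0.221).

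Among list members, Mcm7 fell in wild-type cells by 0.97 and read -0.11 in Rb-null cells (interaction 0.86, adjusted p = 0.0228), and Igfbp3 rose in wild-type and fell in Rb-null cells (interaction -1.22, adjusted p = 0.00631). The Mcm3 probe set that stood for the gene in the replication list read 0.83 (adjusted p = 0.0170). Dbf4, of the same list, went the other way at -1.11 (adjusted p = 0.0105), with every serum-free array at the floor. Fos rose in wild-type cells and read 0.42 in Rb-null cells (interaction -1.38, adjusted p = 0.0203). Ifi202b rose by 1.04 in Rb-null cells and lay at the floor on every wild-type array, so its interaction (adjusted p = 0.00254) is that rise alone, and the brighter probe set of Ccnd1 fell in Rb-null cells, at -0.48, and read -0.05 in wild-type cells (interaction -0.43, adjusted p = 0.0397). Its other probe set went the other way and did not pass (interaction 0.18, adjusted p = 0.751). The Ifi202b call held without any single array. The Mcm7 call held only without wild-type serum 1 or wild-type serum 2, the Ccnd1 call only without wild-type serum 1, and the Fos call only without wild-type serum 1, wild-type serum 3 or wild-type serum-free 2. The Igfbp3 call was lost without wild-type serum-free 1 or 2 or Rb-null serum 1 or 2 (highest adjusted p = 0.0661).

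Among the lists, p53 targets passed upwards with 0 members past the threshold (2 higher adjusted over the list alone, adjusted p = 0.00298, or adjusted p = 0.212 with an estimated correlation). Replication genes passed upwards with 2 higher and 1 lower (11 and 2 adjusted over the list alone, adjusted p = 0.00317), and mitosis genes downwards with 1 lower (2 adjusted over the list alone, adjusted p = 0.00317), both with adjusted p = 0.607 with an estimated correlation. Cytokine genes passed downwards with 1 higher and 2 lower (1 and 4 adjusted over the list alone, adjusted p = 0.00317, or adjusted p = 0.212 with an estimated correlation), as did immediate-early genes with 1 lower (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.00317, or adjusted p = 0.279 with an estimated correlation). Glycolysis and hypoxia genes passed upwards with 1 higher, Ndrg1 at 0.59, held only without wild-type serum 1 (3 adjusted over the list alone, adjusted p = 0.00317, or adjusted p = 0.297 with an estimated correlation). The unfolded protein list passed upwards with 0 members (adjusted p = 0.0214, or adjusted p = 0.607 with an estimated correlation). Luminal markers passed downwards with 0 members (1 higher and 4 lower adjusted over the list alone, adjusted p = 0.0382, or adjusted p = 0.289 with an estimated correlation) and mesenchymal genes downwards with 2 lower, Tnc and Sparc (adjusted p = 0.0382, or adjusted p = 0.279 with an estimated correlation). The mitosis call was lost without wild-type serum 3 (adjusted p = 0.0505) and the glycolysis call without Rb-null serum-free 1 (adjusted p = 0.0911). The luminal call was lost without wild-type serum 2 or 3, wild-type serum-free 1, Rb-null serum 1 or Rb-null serum-free 2 (highest adjusted p = 0.168), and the mesenchymal call without wild-type serum 2 or 3, wild-type serum-free 2 or Rb-null serum-free 1 (0.157). The unfolded protein call was lost without wild-type serum 1 (0.0936), Rb-null serum 2 or Rb-null serum-free 2 (highest 0.435).

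The interaction passed for 90 probe sets, 44 higher and 46 lower in the Rb-null response, and 1059 had an unadjusted p under 0.05. The count was 255 without wild-type serum 1 and fell to 12 without wild-type serum-free 2, 19 without wild-type serum-free 1, 15 without Rb-null serum 1 and 15 without Rb-null serum 2. It was 35 without wild-type serum 2, 48 without wild-type serum 3, 59 without Rb-null serum-free 1 and 32 without Rb-null serum-free 2.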

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

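The tests of array processing, of a weaker response of all cell cycle genes, of the array wild-type serum 1 as a cause and of Rb-null RNA mixed in or swapped were chosen only after the result was seen.

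Some genes had called probe sets in both directions in the averaged genotype difference, such as Csnk1d at 0.64 and -0.53 and Pla2g12a at 0.68 and -0.58, examples picked after the values were seen. These examples did not lie near the threshold, with adjusted p of 0.000129 and 0.00148 for Csnk1d and 6.88e-05 and 0.000236 for Pla2g12a. Small differences near the threshold may explain other such genes. Of the genes with at least 2 probe sets called at 2-fold or more, 0% went both ways, but these were 16 genes, too few to tell. Probe sets that do not follow their named gene could not be excluded as the explanation. Among changes under 2-fold, the withdrawal comparisons had 1.69% of genes called in both directions, against 14.2% in the genotype comparisons. The withdrawal comparisons also called fewer of all probe sets (15.9% and 13.9%) than the genotype comparisons in serum and in serum-free medium (23.6% and 30.7%). Unrelated probe sets of a gene therefore had less chance of both being called on withdrawal. Over all genes with exactly 2 tested probe sets, called or not, these correlated alike in the wild-type withdrawal (r = 0.540) and in the averaged genotype difference (r = 0.499), which goes the other way. Array processing that differed between the lines could not be told: the deviation of wild-type serum 1 followed the genotype difference in these probe sets with a slope of 0.398 (SE 0.0318), under the 0.5 set for it, though above the 0.160 (SE 0.0140) in genes called in 1 direction.

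By the list test at its preset correlation, replication genes fell less and mitosis genes fell more after serum withdrawal in the Rb-null line than in the wild-type line, but neither list passed with an estimated correlation (adjusted p = 0.607 for each), and the mitosis call was lost without wild-type serum 3 (adjusted p = 0.0505). The mitosis list mean had a difference of responses of -0.17 (SE 0.08), opposite to a weaker response of all cell cycle genes. That test restates part of the pattern from which it was drawn, so it does not exclude such a response. Values raised to the floor were excluded for the replication genes, whose difference was 0.22 (SE 0.08) over the genes above the floor on all arrays. The array wild-type serum 1 may account for part of the replication difference, which was 0.10 (SE 0.03) without it and 0.15 (SE 0.08) with it, and this could not be told. For the mitosis genes that array was excluded, since their difference was -0.22 (SE 0.02) without it.

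Wild-type serum 1 stood apart from the other wild-type serum arrays. A distortion by brightness that remained after quantile normalization was excluded, with 1.27% of the variance of the deviation. That normalization gives all arrays the same distribution beforehand, so the test cannot decide about the deposited values. A culture part of the way to the serum-free state was excluded, with a slope of -0.00311 (SE 0.00912). RNA of the Rb-null line mixed in or swapped was excluded, because the 16 probe sets at least 4-fold higher in Rb-null cells needed 0.617% (SE 3.72) of such RNA and the 1424 probe sets from 25% higher up to 2-fold higher needed 51.8% (SE 1.62). The slope of the deviation on the genotype difference over all probe sets, 0.357 (SE 0.00576), and the median deviation of 0.33 over the 197 called probe sets at least 2-fold higher went with such mixing. Array processing shared with the Rb-null arrays stays open: the slope was 0.486 (SE 0.00678) in probe sets that differed under 2-fold and 0.0729 (SE 0.0133) in the others, but that test restates the pattern from which it was drawn and decides nothing.

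Other departures concerned the difference between the lines in the response to serum withdrawal. Mcm3 stood at 1.42, and Mgst1 at 1.54, Nupr1 at 1.48 and Peg3 at 1.48 with part of their values at the floor. Tnc, at the floor on every wild-type array, stood at -2.12, Hspa1b at -2.08, Sparc at -1.81 and Hspa1a at -1.59. List medians were 0.0654 for replication, -0.16 for mitosis, 0.24 for p53 targets, -0.16 for luminal markers and -0.13 for mesenchymal genes. They were -0.14 for cytokines, -0.20 for immediate-early genes, 0.17 for glycolysis and 0.11 for the unfolded protein list.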

How the results depend on the processing

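The combination of an estimated correlation with leaving out wild-type serum 1 was chosen only after the data were seen, and the other alternatives were planned. The sign reversed for Ccne1 alone, whose averaged genotype difference was 0.01 (0.00520, adjusted p = 0.944) in the values as deposited. Of 556 named results called in the main fit, 124 lost the call under some alternative other than leaving out an array or the replicate block. Leaving out an array gave 3068 to 6074 called probe sets for the averaged genotype difference, 877 to 4376 in serum, 1159 to 4981 in serum-free medium, 667 to 1963 on withdrawal in wild-type cells, 497 to 2280 in Rb-null cells and 12 to 255 for the interaction. In groups of 2 it leaves an arm with 1 sample, which is then assumed to vary like the other groups. Array quality weights, whose fit warned that its tolerance was not reached, gave 5544 in serum, 2662 on withdrawal in wild-type cells, 2184 in Rb-null cells and 397 for the interaction. Using only the arrays of the compared groups gave 1505 in serum and 768 on withdrawal in wild-type cells. Asking for at least a 2-fold change left 198 averaged, 198 in serum, 262 in serum-free medium, 145 and 151 on withdrawal in wild-type and Rb-null cells and 29 for the interaction, by construction fewer. The interaction count of 90 rose to 128 with the floor at percentile 40 and fell to 57 with the floor at percentile 10, 59 without a floor, 45 for probe sets with a mean above the median, 57 without the intensity trend and 51 with replicate number as a block. Differences between replicates 1 and 2 correlated from -0.231 to 0.332 between groups, across probe sets, so the replicate numbers were not taken to pair. Except for the 2-fold rule, the cause was not tested. With an estimated correlation no list passed in any comparison.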

Other observations

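The test of chance and the test of chromosomes were set beforehand, and the genes of the next paragraph were picked only after the result was seen.

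Igfbp3 and the heat shock genes were not alone in changing in opposite directions on serum withdrawal. Sh3bgrl2 fell in wild-type cells, at -0.54, and rose in Rb-null cells, at 0.40. Rfc1, the large subunit of the clamp loader for DNA replication, did the same at -0.34 and 0.36, and the neutrophil chemokine Cxcl5 went the other way at 0.36 and -0.33. Their interactions passed with adjusted p of 0.0140, 0.0218 and 0.0330. The highest genotype difference of all belonged to a probe set without a gene name, at 4.71 (SE 0.06), with means of 527 in wild-type and 15310 in Rb-null cells in serum. Another unnamed probe set stood at -2.25.

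Chance in how these arrays fall to the lines was excluded as the source of the number of averaged genotype calls. With the lines exchanged within each medium, 2 of 60 splits, the real one included, called as many probe sets as the real 4377. The highest other split called 4775, more than the real one. It put wild-type serum 1 with all Rb-null arrays and differs from the real split by that array alone. The splits exchange arrays, so they cannot tell a genotype difference from any other difference between these lines.

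Whole chromosomes that differ in copy number between the lines may underlie part of the genotype differences. The medians of 4 of 20 chromosomes lay outside those of random gene sets in the same direction in both media, chromosomes 4 and 7 lower (-0.11 and -0.12) and 13 and 18 higher (0.12 and 0.06). The test left this open, because 4 lies between the 5 set for such a cause and the 1 set against it.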
